A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

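Total RNA of both strains was labelled with Cy3 (JCW27-TOPA-delta sir3) or Cy5 (JCW28-TOPA-delta sir3), per the labels, and hybridised together, with 3 arrays at 0 min and 3 at 120 min from independently grown cultures. Scanner tables were made with GenePix, per the file headers, with a row for each spot. Foreground and local background intensity of each channel are deposited in linear scanner units with no normalization. The percent of saturated pixels per spot is a column of the same deposited tables. A signal-to-noise score and a quality flag score for each spot also come from the scanner software, per the file headers. The deposited series matrix holds log2 ratios, found here to be Cy5 over Cy3 by correlation with each array's own intensities (r = 0.998 to 0.999). Its column medians were -0.05, -0.01 and 0.02 at 0 min and -0.03, 0.03 and -0.04 at 120 min, and whether the authors centred or filtered it further stays unknown. The ratio columns of the scanner tables run Cy5 over Cy3 at 0 min and the other way at 120 min, per the file headers, so only channel intensities were used. The direction rests on the dyes in the labels alone.

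Median foreground was corrected with normexp (offset 50) and each array normalised by loess in limma 3.58.1 under R 4.3.3. Spots with a bad flag and 664 control spots, 280 of them empty, had no weight in the loess and were left out. Spots of a gene were averaged, giving 6388 genes, of which 6100 had values on at least 2 arrays at each time and were tested. Of the gene identifiers, 5849 matched the R64 assembly's gene table, which supplied standard names and coding lengths, and 539 kept the file's name. The files name no genome build, so distance in bases was not used, and distance was counted in systematic gene names from the end of each arm, the fallback fixed in the design. Chromosome arms with under 5 genes on either side (3 arms) were left out.

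Ratios were fitted with lmFit and eBayes over all 6 arrays, with 4 residual degrees of freedom, and p-values adjusted by the Benjamini-Hochberg method. The change is the 120 min mean minus the 0 min mean. Gene lists were tested with camera at a preset correlation of 0.01, and then with an estimated correlation and with fry. Of 32 lists fixed before the data were examined, 31 had at least 5 measured members. End shifts and the length trend were tested by sign flips over arms with 100000 resamples. Coding length came from the R64 table. A gene was above background at a mean signal-to-noise of 3 or more. Where a gene was below this on every array of a time in a channel, only a bound is given, computed per channel after loess and Aquantile and open to dye bias.

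Genes were named by a rule fixed before the data were examined. For the change these were the 12 largest rises and 12 largest falls past the threshold, measured on all 6 arrays with no overlap between the times, and for each time the 6 highest and 6 lowest with the same sign on its 3 arrays. Standard names were required, each list described was given up to 4 further examples of its own (the 2 largest rises and 2 largest falls), and TOP1, TOP2, SIR3 and LEU2 were always included. A gene that the rule picks is not reported here. On simulated values for 6100 genes, the change test recovered 80.6% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2, with 9 unchanged genes called. A simulated end shift of 0.4 was recovered as 0.401. The simulated values were independent between genes and needed no normalization, and in the gene test most genes were unchanged. They check the code and do not give the error rates of the real data.

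The replicate SD of the log2 ratio was 0.12 at 0 min and 0.185 at 120 min, against 0.0536 to 0.0795 between duplicate spots, and the number of arrays limits the precision. The 0 min arrays were scanned on 1 day and the 120 min arrays on 2 others, so scan day and time cannot be told apart. Alternatives covered the direction of the dyes, background correction, normalization, filters, the replicate number or scan day as a block, thresholds, leaving out each array, and other definitions of chromosome ends.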

Results

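Transcript levels were compared between a pair of budding yeast strains on 6 spotted arrays, each read in 2 colours. Per the labels, both strains lacked the topoisomerase gene TOP1 and the silencing gene SIR3, and both carried a plasmid with the bacterial topoisomerase TOPA, which relaxes negative but not positive supercoils. The control strain, JCW27-TOPA-delta sir3 (JCW27 below), had normal TOP2, and the other, JCW28-TOPA-delta sir3 (JCW28 below), had the temperature-sensitive allele top2-4. Cultures were sampled in log phase at 26 °C (0 min, 3 arrays) and after 120 min at 35 °C, where top2-4 is inactive (3 arrays). Per the labels, JCW28 carried Cy5 and JCW27 Cy3 on every array, and each ratio is given as top2-4 over control on that basis. The question set by the design is how transcription responds when positive supercoils build up in cells labelled as lacking telomere silencing. Each array had 13824 spots, of which 840 to 2121 carried a bad flag. Between 66.5 and 89.1% of genes were above background in Cy5, and between 72.6 and 88.8% in Cy3, with the lowest shares on 120 min replicate 2. Ratios correlated across genes at r = 0.964 to 0.971 among the 0 min arrays and 0.954 to 0.973 among the 120 min arrays, against 0.631 to 0.663 between times.

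The genes of the genotype were read first. TOP2 was above background in both channels on the 3 arrays at 0 min, with signal-to-noise between 8.52 and 26.2. At 120 min the scanner software found neither of its 2 spots on any of the 3 arrays, in strains that both carry the gene, so TOP2 has no ratio there and no change is given. It was the only gene of 6388 with every spot not found on all 120 min arrays and both channels above background on all 0 min arrays. SIR3 gave signal in both channels at both times, with signal-to-noise between 13.6 and 61.8 and a signal of 196 to 549.5, near or above the array medians of 168 to 227, in strains labelled as lacking it. TOP1 was dimmer, between 2.13 and 14.9. Which part of each gene the probes cover is not given in the sources used here, so these signals, which run against the labels if the probes lie in deleted parts, do not settle the deletions. LEU2, the marker selected in the medium, was 1.88-fold higher in top2-4 at 0 min (log2 ratio 0.91 ± 0.05, SD, n = 3) and did not pass the test at 120 min (0.09 ± 0.15, n = 3). It did pass there without background correction (0.15), with plain subtraction (0.26), with an offset of 0 (0.18) and with print-tip loess (0.77). Between the times it fell by 0.82 ± 0.09 (SE), a fall that print-tip loess did not keep. SIR3 was 1.47-fold lower in top2-4 at 0 min and its change did not pass the test (0.13 ± 0.09, adjusted p = 0.247), except after scale normalization (0.33, adjusted p = 0.00953), while TOP1 fell by 0.36 ± 0.09 between the times (adjusted p = 0.0093).

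Genes near chromosome ends rose relative to genes farther inside between 0 and 120 min, in top2-4 against the control. Each array is centred near 0, so only the difference between end and interior genes is measured, and a rise of one sets the other lower. Among the 50 endmost gene names of each chromosome arm, the median log2 change was 0.32 over 1578 genes, against -0.16 over 4494 interior genes. The shift of end against interior genes, taken arm by arm, averaged 0.41 ± 0.19 (SD over 29 arms), a 1.33-fold difference, and was above 0 in 29 of 29 arms (sign-flip permutation test over arms, two-sided, p = 1e-05, the smallest it can give). By the same permutation test the shift was -0.02 ± 0.09 at 0 min, above 0 in 16 of 29 arms (p = 0.186), and 0.41 ± 0.16 at 120 min, above 0 in 29 of 29 (p = 1e-05). Per array it averaged -0.02 ± 0.004 at 0 min and 0.42 ± 0.07 at 120 min (SD, n = 3 each), and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. The size of the shift depended on background handling, and plain subtraction gave 0.70 for the change. The deposited matrix values, which differ in genes and in processing at once, gave 0.75, and on their 4267 tested genes the values used here gave 0.53. The sign rests on the dyes of the labels: with the dyes exchanged at 120 min the shift of the change was -0.38.

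**Figure D1:**
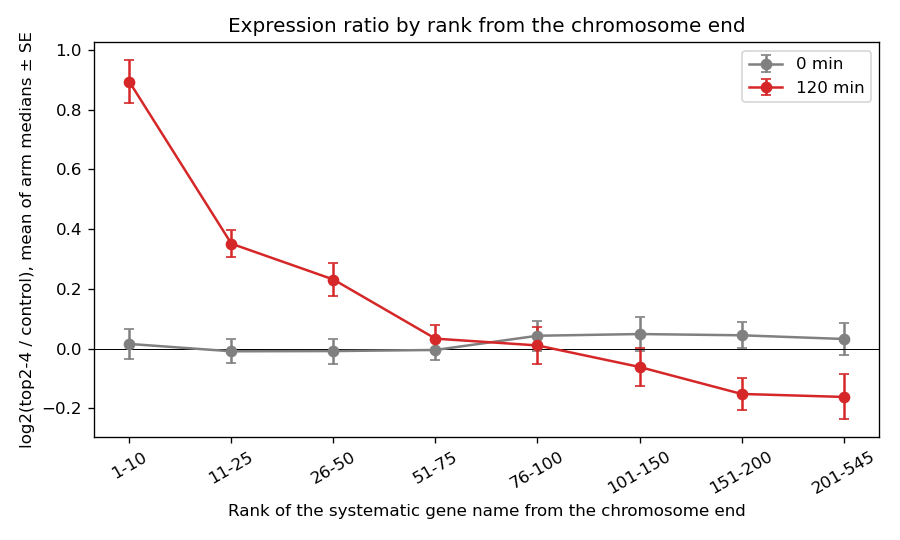
Mean over chromosome arms of the arm median log2 ratio of top2-4 over control (points, with standard errors over arms) against rank of the gene name from the chromosome end, at 0 min (grey) and 120 min (red). At 120 min the 10 endmost names average 0.89 and ranks 201 to 545 average -0.16 (32 and 14 arms).

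The profile fell with distance from the end. The 10 endmost names of each arm changed by a median of 0.88 (328 genes, 85.4% higher and 1.83% lower at the gene test). Names ranked 11 to 25 changed by 0.34, those ranked 26 to 50 by 0.18 and those ranked 51 to 75 by 0.03, and from rank 201 the median was -0.24 over 1540 genes. Of the end genes, 879 of 1578 rose and 149 fell, and of the interior genes, 695 of 4494 rose and 1871 fell. The odds of a rise were 6.87 times higher among end genes (Fisher's exact test, p = 4.97e-200), a test that counts neighbouring genes as independent. The directions of this profile and of these counts rest on the labelled dyes, as does the sign of the shift.

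Lists built around gene families of chromosome ends carried large rises. Some members lie inside an arm by their systematic names, such as COS111, SNZ1 (-1.63 at 0 min, -0.50 at 120 min) and TIR4. TIR4 stood at 0.64 and 2.14, with Cy3 not well above background on 1 of 3 arrays at 0 min. Family and position are thus not told apart within these lists. All 28 measured seripauperin and cell wall mannoprotein genes rose, with a median log2 change of 1.91, among them PAU6 (2.29 ± 0.09, SE) and PAU10 (2.19 ± 0.07). Of 11 COS genes, 10 rose, with COS6 at 1.81 ± 0.11 and COS4 at 1.68 ± 0.09, and COS111 fell by 0.29 ± 0.09. Of 59 genes in other end families, 54 rose and 0 fell, including MAL33, an activator of maltose genes (1.85 ± 0.12), and the maltase MAL12 (1.68 ± 0.17, with Cy3 not well above background on 2 of 3 arrays at 0 min). Members of these families are close copies, so 1 transcript can hybridise to several probes. With the dyes exchanged at 120 min the medians of the seripauperin, COS and other end lists were -1.48, -0.58 and -0.89. The set test camera called all 3 lists (adjusted p = 1.4e-17, 9.71e-06 and 5.81e-16). None of these calls held with an estimated correlation, with adjusted p = 0.196, 0.196 and 0.333.

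Between the times, 1583 of 6100 tested genes rose and 2021 fell in top2-4 relative to the control (limma, Benjamini-Hochberg adjusted p under 0.05), 309 and 354 of them at least 2-fold. The largest rise was in DLD3, a lactate dehydrogenase, which went from -1.75 ± 0.11 at 0 min to 1.85 ± 0.11 at 120 min (SD, n = 3 each), a 12.2-fold change. YAT1, a carnitine acetyltransferase, rose 10.7-fold, with the control channel not well above background on 1 of 3 arrays at 120 min. The next were mixed in function. The methionine permease MUP3 rose 7.96-fold, the sulfur regulator MET28 7.40-fold and the sulfite reductase subunit MET10 6.53-fold. The polyamine exporter TPO1 rose 6.03-fold, and the permeases DIP5 and GAP1 5.77-fold and 5.70-fold. MTD1 rose 5.45-fold, NRE1 5.31-fold, HSP31 5.02-fold and PAU6 4.87-fold. Adjusted p for these 12 genes ranged up to 0.000237, for TPO1. With the dyes exchanged at 120 min, DLD3 (-0.10), MET10 (0.25) and TPO1 (0.14) were not called, and GAP1 still rose (1.38). The others were then called as falls, among them YAT1 (-4.3) and NRE1 (-5.8).

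Of the 12 largest falls, 7 were in ribosomal protein genes. RPL15B fell 7.23-fold, RPL3 7.17-fold, RPL30 7.01-fold, RPL4B 5.82-fold, RPL4A 5.72-fold, RPS2 5.31-fold and RPL9A 5.20-fold. TMA19, a ribosome-associated protein, fell 6.82-fold, and YEF3, a translation elongation factor, fell 6.26-fold. The wall proteins CCW12 and CWP2 fell 5.78-fold and 5.21-fold, and NCE103, the carbonic anhydrase, fell 5.65-fold. By systematic name, all of these 12 falls were in interior genes. With the dyes exchanged at 120 min these 7 ribosomal protein genes rose, by 1.96 to 3.37. RPL3 went from 0.40 ± 0.05 at 0 min to -2.44 ± 0.05 at 120 min (SD, n = 3 each).

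Of 134 cytosolic ribosomal protein genes, 133 fell and 0 rose, over all genes and adjusted over the list alone, with a median change of -1.62. With the dyes exchanged at 120 min only 6 fell, and the median change was 1.5. Of 138 ribosome biogenesis genes, 100 fell and 3 rose, or 103 and 5 adjusted over the list alone, with NOP56 at -1.41 ± 0.08 and UTP8 at -1.21 ± 0.10 (SE). Subunits of RNA polymerases I and III fell in 14 of 18 cases and rose in 1, led by RPA135 (-1.32 ± 0.08). Of 12 RNA polymerase II subunits 8 fell, or 9 adjusted over the list alone, led by RPB10 (-0.94 ± 0.12). Of 11 histone genes 10 fell, with HTA1 at -2.15 ± 0.14 and HTA2 at -2.01 ± 0.08, and the list median was -1.59. Camera called these 5 lists, with adjusted p between 1.05e-38 for the ribosomal proteins and 0.00954 for RNA polymerase II. With an estimated correlation none was called: adjusted p = 0.196 for ribosomal proteins and histones, 0.34 for ribosome biogenesis and 0.333 for both polymerase lists. Under exchanged dyes at 120 min 10 histone genes rose and 1 fell (median 0.48), the ribosome biogenesis median was 0.96 with 20 genes lower, 15 genes of RNA polymerases I and III rose and 1 fell, and RNA polymerase II was not called (adjusted p = 0.672).

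Among metabolic lists, 19 of 29 sulfur and methionine genes rose and 5 fell (median 1.00), with MET13 at -1.39 ± 0.20 and SAM1 at -1.13 ± 0.09 (SE) going down. Glycolytic and fermentation genes rose in 12 of 20 cases, with HXK2 at 1.90 ± 0.10, while the pyruvate decarboxylases PDC1 (-2.05 ± 0.10) and PDC5 (-1.69 ± 0.09) fell. Of 27 iron regulon genes 12 rose and 4 fell, with FIT3 at 2.21 ± 0.11 and ENB1 at 1.83 ± 0.08. Amino acid biosynthesis genes fell in 37 of 65 cases and rose in 11, with LYS12 at -1.55 ± 0.16 and GDH3 at 1.99 ± 0.08. Oxidative phosphorylation genes fell in 37 of 63 cases (39 adjusted over the list alone) and rose in 8, with QCR9 at -1.34 ± 0.08 and CYC7 at 1.24 ± 0.08. Of 20 long, highly transcribed genes 14 fell and 2 rose, with PMA1 at -2.14 ± 0.14 and TOR2 at 0.62 ± 0.07. Camera called these 6 lists (adjusted p between 2.16e-05 and 0.0092), and with an estimated correlation adjusted p = 0.196 for the sulfur, iron and long gene lists, 0.392 for glycolysis, 0.333 for amino acid biosynthesis and 0.275 for oxidative phosphorylation. The amino acid call was also lost under median centring (adjusted p = 0.125) and with the matrix values (0.0763). Under exchanged dyes at 120 min the sulfur (adjusted p = 0.127), glycolysis (0.0841) and iron (0.639) lists were not called, 54 amino acid genes rose and 6 fell, 4 oxidative phosphorylation genes rose and 53 fell, and 15 long genes rose and 3 fell.

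Smaller shifts were called for G2/M genes (17 of 31 rose, 7 fell, with IQG1 at 1.30 ± 0.17 and CDC20 at -0.85 ± 0.11, SE), pheromone response genes (14 of 32 rose, 2 fell, with PRM1 at 2.02 ± 0.15) and meiosis genes (18 of 50 rose, 6 fell, with SPS100 at 1.81 ± 0.17). Their adjusted p under camera was 0.0104, 0.00382 and 0.0104, and with an estimated correlation adjusted p = 0.333, 0.333 and 0.352. The G2/M call was also lost without the dimmest 25% of genes (adjusted p = 0.0764) and with the matrix values (0.33), and the meiosis call under median centring (0.0667). Exchanged dyes at 120 min gave 25 G2/M genes higher and 5 lower, 6 pheromone genes higher and 16 lower with no call (adjusted p = 0.136), and 8 meiosis genes higher and 26 lower. In all, camera called 17 of 31 lists, 9 higher and 8 lower. With an estimated correlation, a test with 4 residual degrees of freedom, 0 of the 17 were called. Fry, which asks another question, called 26 lists. The DNA damage list was not called (adjusted p = 0.233), with HUG1 at 1.63 ± 0.10 and RNR1 at -0.80 ± 0.14. Nor were the heat shock chaperones (adjusted p = 0.25), with HCH1 at 1.76 ± 0.10 and HSP60 at -0.59 ± 0.07, though this list was called higher under median centring (adjusted p = 0.00254), with the matrix values (0.0286) and by fry (0.0262). The general stress list was not called either (adjusted p = 0.777), with 19 of 52 members higher and 21 lower, a median of -0.08 and a mean of 0.03. Among 12 alternatives of processing and test it was called higher with the matrix values alone (adjusted p = 0.0245). With the dyes exchanged at 120 min it was called lower, with 3 members higher and 47 lower (camera, adjusted p = 1.44e-15).

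The other lists were not called in the change under the labelled dyes. With the dyes exchanged at 120 min, camera called G1/S (28 rose, 5 fell, adjusted p = 0.000455) and ergosterol genes (22 and 4, 0.000389). It also called hexose transporters (1 rose, 13 fell, adjusted p = 0.000438), TCA and glyoxylate genes (7 and 22, 0.000519) and M/G1 genes (18 and 7, 0.0465). The rest of these lists then had adjusted p of 0.228 or more. Among cell cycle lists, G1/S genes went both ways (11 of 38 rose and 10 fell, adjusted p = 0.798), with the wall enzyme CRH1 at -2.33 ± 0.07 and NRM1 at 1.09 ± 0.09 (SE). Of 28 M/G1 genes 13 fell and 5 rose (adjusted p = 0.273), with the chitinase CTS1 at -2.13 ± 0.08. Cell wall integrity genes split into 11 higher and 16 lower of 35 (adjusted p = 0.408), with the protease YPS6 at 2.01 ± 0.17. Hexose transporters had a median of 0.24 and a mean of -0.10 (8 of 17 rose, 6 fell), with HXT9 at 1.15 ± 0.15 and HXT6 at -1.60 ± 0.10. Of 29 genes of the TCA and glyoxylate cycles 14 rose and 9 fell (adjusted p = 0.267), with ACS1 at 1.37 ± 0.11. Of 30 ergosterol genes 8 rose and 13 fell (adjusted p = 0.475), with ERG3 at -1.01 ± 0.11. Of 37 proteasome genes 7 rose and 12 fell (adjusted p = 0.623), with PRE9 at -1.09 ± 0.10. Phosphate genes rose in 11 of 21 cases and fell in 3 (adjusted p = 0.06), with PHO4 at 0.86 ± 0.10. The phosphate list was called without the dimmest 25% of genes (adjusted p = 0.0441), without 120 min replicate 1 (0.0403), without 120 min replicate 3 (0.0291) and by fry (0.00172).

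Purine genes went both ways (8 of 19 rose, 7 fell), with ADE1 at 1.65 ± 0.07 and GUA1 at -1.45 ± 0.10 (SE). Of 7 galactose genes 3 rose and 1 fell, and the fall was in GCY1 (-0.62 ± 0.13). Of 7 genes of the mating-type locus and the silent cassettes 3 rose and 0 fell, among them HMRA2 (0.50 ± 0.11) and MATALPHA2 (0.36 ± 0.11). Adjusted p under camera was 0.475, 0.148 and 0.18 for these 3 lists. By fry, of the lists that camera did not call, those of DNA damage (adjusted p = 0.0068), M/G1 (0.000462), cell wall integrity (0.00121), purine (0.00185), mating-type (0.00923), galactose (0.0291) and hexose transporter genes (0.0325) were also called.

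**Figure D2:**
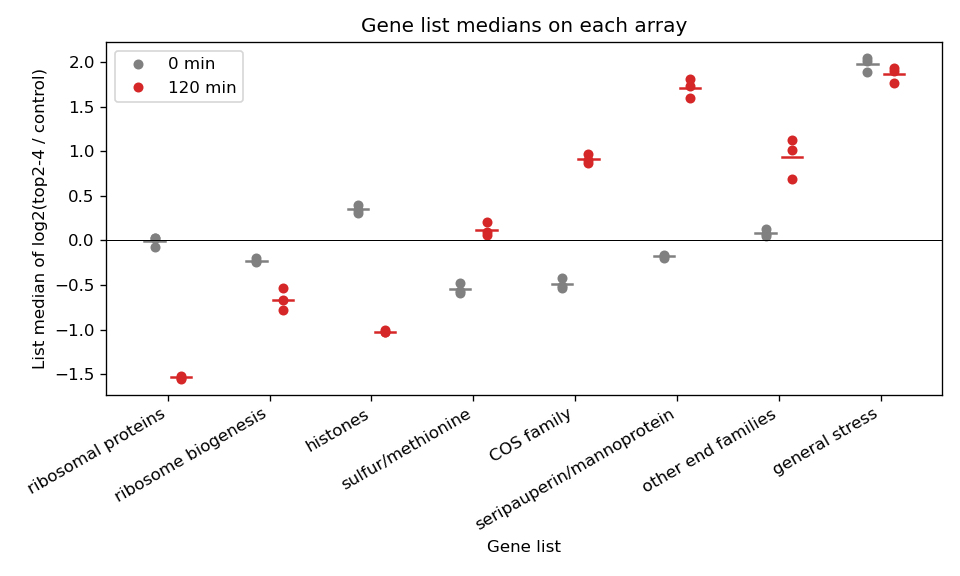
Median log2 ratio of top2-4 over control of 8 gene lists on each of the 6 arrays (points, 3 at 0 min in grey and 3 at 120 min in red), with the mean per time as a line. The ribosomal protein list has a median change of -1.62 and the seripauperin and mannoprotein list one of 1.91.

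The strains already differed at 0 min, where 1932 genes were higher and 1931 lower in top2-4, 390 and 134 of them at least 2-fold. Highest was OLI1, a mitochondrially encoded ATP synthase subunit, which was not well above background in the control channel and was at least 125-fold higher (adjusted p = 1.73e-09). The stress gene DDR2 was 42.4-fold higher, the aldehyde dehydrogenase ALD3 29.7-fold, EGO4 26.4-fold, GAC1 23.5-fold and FMP45 23.5-fold. Lowest were ALD5 (7.12-fold lower), GSC2 (5.95-fold), ASP3-3 (5.42-fold), DIA1 (5.16-fold), the serine pathway enzyme SER3 (5.12-fold) and glutamine synthetase GLN1 (4.91-fold). Of 52 general stress genes 45 were higher, with a median log2 ratio of 1.98, and of 63 oxidative phosphorylation genes 55 were higher (median 1.10). Of 65 amino acid biosynthesis genes 49 were lower (median -0.76), and of 29 sulfur genes 21 were lower, including MET17 at -2.24 ± 0.09 (SE). Camera called these 4 lists (adjusted p between 1.74e-18 and 7.39e-06), and with an estimated correlation adjusted p = 0.208, 0.192, 0.208 and 0.208.

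Other lists called lower at 0 min were ribosome biogenesis (80 of 138 genes, or 82 adjusted over the list alone), G1/S (22 of 38), G2/M (22 of 31), ergosterol (22 of 30), RNA polymerases I and III (11 of 18) and the COS family (9 of 11). Lists called higher were hexose transporters (11 of 17), the TCA and glyoxylate cycles (21 of 29) and histones (7 of 11, median 0.41, adjusted p = 0.0442). With an estimated correlation none of these 9 held (adjusted p = 0.23 or more). The histone call was lost in 8 of 12 alternatives, with adjusted p up to 0.662 under median centring. The ribosomal protein list had 40 of 134 genes higher and 40 lower and a median of 0.01, but was called lower under median centring (adjusted p = 5.72e-06) and with the matrix values (0.00517). Since the labels give no array with exchanged dyes, the ratios at a single time are open to dye bias, which the change between times removes where it is constant and the labels hold.

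At 120 min 2307 genes were higher and 2407 lower in top2-4, 587 and 488 of them at least 2-fold. OLI1 was at least 158-fold higher, DDR2 46.4-fold, the wall protein PIR3 45.0-fold, hexokinase HXK1 30.5-fold and MSC1 24.7-fold. AI5_ALPHA, a mitochondrially encoded intron product, was at least 23.5-fold higher. Among the lowest were RPL15B (8.65-fold lower), the lysine gene LYS2 (8.44-fold, not well above background in Cy5 on 1 of 3 arrays), ALD5 (8.08-fold), YEF3 (7.64-fold) and ARG56 (6.97-fold). Of 134 ribosomal protein genes 132 were lower, and all 28 seripauperin and mannoprotein genes were higher. General stress genes were higher in 47 of 52 cases (median 1.88). Camera called these 3 lists (adjusted p = 2.33e-29, 5.48e-12 and 1.01e-13), and with an estimated correlation adjusted p = 0.181 for each. Also lower were amino acid biosynthesis (54 of 65 genes, median -0.90), ribosome biogenesis (116 of 138) and all 18 subunits of RNA polymerases I and III, and higher were other end families (55 of 59) and COS genes (10 of 11). These 5 calls had adjusted p from 1.84e-11 to 0.000533, and with an estimated correlation adjusted p = 0.181, 0.327, 0.264, 0.352 and 0.264. Camera called 19 of 31 lists at 120 min, 10 higher and 9 lower, and 0 of the 19 held with an estimated correlation. Among them, oxidative phosphorylation genes were still higher in 40 of 63 cases and lower in 7 (camera, adjusted p = 1.73e-05). Histone genes were lower in 9 of 11 cases (camera, adjusted p = 0.00062). In all 1318 genes were higher at both times and 1278 lower at both, against 731 and 762 for independent lists, and 291 were higher then lower and 271 lower then higher. These counts too rest on the labelled dyes, since exchanged dyes at 120 min would turn the 1318 and 1278 into opposite calls.

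Under the labelled dyes, change between the times rose weakly with coding length. Spearman's rho across genes, taken per chromosome arm, averaged 0.13 ± 0.10 (SD over 32 arms, 5600 genes) and was below 0 in 4 arms (sign-flip permutation test over arms, two-sided, p = 1e-05, the smallest it can give). Genes within an arm are not independent replicates. All 32 arms were read on the same 6 arrays, so this p does not measure the spread between arrays. No test over arrays is given for the trend. The fixed list of long, highly transcribed genes went the other way, with 14 of 20 lower and a median change of -0.45. The sign of the trend rests on the labelled dyes, and no value with exchanged dyes is given for it.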

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

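The tests of the end shift by matched intensity and without list genes were chosen after the end shift was seen, before their own outcomes, and the exchanged dyes were tried after all results, while print-tip loess and the splits were planned. Several results differed between 0 and 120 min in the same strain contrast. The chromosome-end shift changed by 0.41 between the times. The histone list had a median change of -1.59 and the COS family one of 1.48, each called in opposite directions at 0 and 120 min by camera. With an estimated correlation these calls were lost, with adjusted p = 0.33 and 0.181 for histones and 0.504 and 0.264 for COS. Genes with opposite called directions were DLD3 (change 3.60), MET10 (2.71), TPO1 (2.59), DIP5 (2.53), GAP1 (2.51), PAU6 (2.29), RPL3 (-2.84), TMA19 (-2.77), RPL4B (-2.54), CCW12 (-2.53), RPL4A (-2.52), NCE103 (-2.50) and CWP2 (-2.38). The histone call at 0 min was lost in 8 of 12 alternatives.

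The rise at chromosome ends is relative to interior genes, so a fall of interior genes with the ends unchanged would look the same. The shift may be a response to loss of Top2 activity at 120 min, a hypothesis not tested here. Tests were run for 3 technical explanations. With the interior median of each gene's intensity class subtracted, the shift was 0.415 ± 0.189 (SD over 29 arms). Loess had already removed the trend with intensity from each array. This test could therefore hardly lower the shift, and does not decide on the low signal of end genes. Without the 1089 genes of the fixed lists the shift was 0.39 ± 0.18, and under print-tip loess 0.373 ± 0.178. These values argue against list membership and spot placement as its whole cause. Scan day and slide set stay open, since each time had days of its own. Both strains went through the shift in temperature and were hybridised together, so an equal response of both cancels in the ratio. No biological cause was separated from a response to temperature that differs between the strains.

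For the counts, 1 of the 10 splits of the 6 arrays into 3 and 3 gave as many changed genes as the real split, which is the real one: 3604, against 0 in the highest other split. Among the 4 assignments of channels at each time, 1 gave as many, again the real one, with 3863 at 0 min and 4714 at 120 min against 0 in the highest other. So few splits cannot give a share under 0.05.

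A bright control feature outside the gene set also stood apart. Its 32 spots per array had a median log2 Cy5 over Cy3 that averaged 1.30 ± 0.06 at 0 min and -1.60 ± 0.02 at 120 min (SD, n = 3 each). What it measures is not known here. The ratio columns of the scanner tables also turned over between the times, per the file headers. Of 500 nuclear genes at least 2-fold different at 0 min, 472 kept their sign at 120 min under the labelled dyes, which a dye bias of single genes would also give, so this does not decide the direction. The dyes of the labels were kept, no other record of them was used, and exchanged dyes at 120 min would turn every ratio there. With them the end shift of the change was -0.38, and of the 24 genes named for the change 18 were called in the opposite direction, 3 in the same one and 3 not at all. DLD3 then changed by -0.10. As many lists, 17, were called by camera, and the ribosomal protein list had a median of 1.5 and the general stress list one of -3.93.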

How the results depend on the processing

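The foreground mean, the counts of 25 and 75 end names, the omission of 12 endmost names, the R64 gene order and the omission of list genes, ribosomal proteins or mitochondrially encoded genes, and the exchanged dyes, were chosen after seeing the data. Distances of 50, 100 and 150 kb, and the omission of genes within 25 kb, were not run, since the files name no build. Under the alternatives 255 values of the main results kept direction and side of the threshold, or stayed within 1.5 times the main count, and 5 did not. The number of lists called in the change, 17, was 0 with an estimated correlation, whose 4 residual degrees of freedom widen it for every list, and 26 with fry, which asks another question. With the dyes exchanged at 120 min, which turns those ratios by construction, the end shift was -0.41 at 120 min and -0.38 in the change, and 2471 genes rose. Under all other alternatives the end shift of the change stayed above 0 and ran from 0.32 to 0.75, highest with the deposited matrix values. Aquantile after loess leaves ratios as they are and tests nothing here. Without each array in turn, 1279 to 1746 genes rose and 1708 to 2142 fell. Same-numbered arrays had deviation correlations of 0.025, 0.129 and -0.04. These gave no sign that the numbers pair arrays, but with 3 arrays per time they cannot exclude it. With the replicate block 1548 genes rose and 1957 fell. With scan day as a random block 1649 rose and 2093 fell, at an estimated correlation within days of -0.06. Each day held arrays of a single time, so this block cannot remove a day effect from the change.

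These results also turned direction, and the cause was not tested. The ribosomal protein list at 0 min, not called in the main setting, was called lower with a median of -0.31 under median centring and -0.24 with the matrix values. Under fry the galactose list at 0 min (median -0.11) and the hexose transporter list in the change (median 0.24) went the other way, being lists whose median and mean differ in sign. LEU2 changed by 0.22 under print-tip loess (adjusted p = 0.0596). Signal limits dim genes: between 66.5 and 89.1% of genes were above background in Cy5 on an array.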

Other observations

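The tests in this part were chosen after the results were seen. All 18 mitochondrially encoded genes with a standard name, a list chosen after their values were seen, were higher in top2-4 at both times. Of these, 13 were not well above background in the control channel on any of the 3 arrays at 0 min, and 13 at 120 min, so most ratios are bounds and no median is given. ATP6 stood at 3.03 ± 0.20 and 2.96 ± 0.86 (SD, n = 3 each), while COX2, not well above background in the control channel, was at least 7.55-fold and at least 8.13-fold higher. The list left out 10 mitochondrial probes without a gene name, of which 7 were higher at 0 min and 9 at 120 min. Apart from the mitochondrially encoded genes, 50 of 58 nuclear oxidative phosphorylation genes were still higher at 0 min, with a median of 1.04.

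Of 15 mitochondrially encoded genes above background in Cy5 on all 6 arrays, 9 were under it in Cy3 on all 6. Among 3775 nuclear genes bright in Cy5 the number was 6 (Fisher's exact test, p = 5.64e-20), which argues against a dye bias shared with nuclear genes. That test counts the genes as independent, which an intron product and the gene that holds it are not. With the probes lacking a name included, 14 of 21 mitochondrial probes above background in Cy5 were under it in Cy3 on all 6 arrays. A candidate explanation is that the control cultures expressed little of the mitochondrial genome. Cells that lose mitochondrial function raise retrograde response genes, and 3 of 4 such genes were lower in top2-4 at 0 min, DLD3, CIT2 and PDH1, while ATO3 did not pass the test (-0.17 ± 0.08, n = 3). At 120 min those 3 were higher in top2-4 and ATO3 was lower, so this explanation stays open, as does a dye bias particular to mitochondrial transcripts.

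General stress genes had a median log2 ratio of 1.98 at 0 min, before the shift in temperature. The highest median of 10000 random lists matched on intensity was 0.438. Loess had already removed a trend with intensity from each array, so such lists have low medians by construction. The comparison therefore cannot test a dye bias that follows intensity. Across the 52 genes the ratios at both times correlated at r = 0.821. A dye bias of single genes and a difference between the strains stay open.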
